A study of Mus musculus with 21 samples.

How the data were processed

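The authors sorted Nestin-EGFP positive cells, isolated polyadenylated RNA with a magnetic bead kit, made standard libraries and sequenced them on an Illumina HiSeq instrument. Per the submitters' processing notes, TopHat, Bowtie2, Cufflinks and Cuffdiff were used with the mm10 genome. Their versions were not given in the sources used here. The deposited tables gave 1 expression value per gene symbol and library, and these values, not the reads, were the starting point here. The deposited 12-week tables named FPKM in their headers. The headers of the E15 and P5 tables named only the sample, and FPKM was inferred as their unit from the same genes, the same range of values and the same column sums. Those sums were 465610 to 506183 at E15, 475775 to 492041 at P5 and 482753 to 574594 at 12 weeks.

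All 21 libraries and all 24322 symbols were read, and no sample column was left unused. Symbols were placed on mm10 with GENCODE vM21, in which 23185 matched a single gene. No strand was stated for the libraries, so reads from antisense or overlapping transcripts and from close paralogues may have been counted toward a named gene. Values were analysed as log2(FPKM + 1), and the added 1 understates the change of genes at low values. A gene was kept for a fit when it had at least 1 FPKM in at least 3 libraries of that fit.

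The groups, comparisons, thresholds, the gene lists tested by camera and all alternatives not marked as added were set before the data were examined. VPA was compared with control within each age, with 6 libraries at E15 and at P5 and 9 at 12 weeks, where the running group was in the same fit. Control libraries were compared between ages, and differences in the VPA effect between ages were tested as interactions, in a fit of all 21 libraries. Linear models were fitted with limma 3.58.1 in R 4.3.3, with lmFit and with eBayes using an intensity trend. P values were adjusted by the Benjamini-Hochberg method over the tested genes of a comparison, with a threshold of 0.05. For the interactions, values counted as not overlapping when the pair of groups did not overlap at either age. It is not known whether the replicates were separate litters or parts of a pool, so the p values measure spread among samples that may be technical. At 12 weeks every library held both Xist and Ddx3y, with Xist at 52.9 or more and Ddx3y at 6.42 or more, so each came from more than 1 animal.

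Fixed lists of marker and pathway genes, 38 in number, were tested when at least 5 members were kept, which left 28 to 37 per comparison. The list of mitochondrially encoded genes had no tested members. Each list was tested against all other tested genes by camera with a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and the self-contained test fry were run beside it. Of 357 tests of lists 140 passed with the preset correlation, 12 with the estimated correlation and 59 by fry. Calls of list members were also made after adjusting over the list alone.

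Genes were named by rule. The 10 largest rises and the 10 largest falls past the threshold with non-overlapping groups and a mean of at least 5 FPKM in the higher group were taken, leaving out numbered gene models. Up to 2 members of each list in each direction were added, and Nes and Cxcr4 were always given. Where fewer than 5 genes passed in a direction, the 5 with the smallest p were given by value only, and 2 members were given for a list called without any member past the threshold. The text names those from the top of each part. Other genes are marked as chosen after their values were seen.

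Alternatives changed 1 setting at a time: a pseudocount of 0.1, no filter, a filter at 5 FPKM, median-of-ratios or quantile scaling, array quality weights, a block for replicate number, no trend, a fit of all libraries or of only the groups compared, and the removal of each library in turn. Added after the data were seen were the removal of small RNA genes, a covariate for libraries without Y-linked transcripts at E15 and P5, the removal of each running library for VPA against control at 12 weeks, and counts of list members. The opposite direction of VPA and running was set against 20 simulated data sets with no effect and 100 regroupings of the 9 libraries, which gave correlations from -0.746 to -0.284, with 45 as low as the real one.

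Sequencing depth was not used here as read counts were not analysed. Relative depth was estimated from ratios of values below 2 FPKM, which cluster when they stem from single fragments. It was 0.966 to 1.4 at E15 and 0.678 to 1.33 at P5, relative to E15 control rep1, from clusters of 174 to 412 genes. At 12 weeks the clusters were small, with 9 to 27 genes or 1.11% to 4.87% of those compared, and gave 0.563 to 2.11, lowest in running rep3. Small RNA genes held 12.9% to 14.9% of the column sums at E15, 15% to 16.6% at P5 and 13% to 27.7% at 12 weeks, highest in running rep3, which also had the fewest genes above 0. Correlations between replicates were 0.899 to 0.942 at E15, 0.921 to 0.931 at P5 and 0.708 to 0.853 at 12 weeks. Actb, Gapdh, Eef1a1 and Ppia were above 0 in every library, and of 80 ribosomal protein genes 2 to 6 were listed at 0 in each library.

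Each comparison was tested on simulated data with 200 genes changed, all with a mean log2(FPKM + 1) of at least 2. Genes were drawn independently, each with 1 observed SD shared by all groups of the fit. Of genes with a simulated log2 change of 1, 88% were recovered at E15 and 91% at P5, but 10% for VPA at 12 weeks, 13% for running against VPA and 12% for running against control. At a log2 change of 2 these shares were 98%, 97%, 44%, 57% and 45%. For the ages they were 44% and 45% at a change of 1 and 93% and 92% at 2. For the interactions they were 18%, 23% and 21% at 1 and 79%, 72% and 73% at 2. With no simulated change, at most 1 gene was called. These values do not cover unequal spread between groups or genes that move together.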

Results

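Nestin-EGFP positive cells were sorted by flow cytometry from C57BL/6 mice whose mothers had received methylcellulose or valproic acid (VPA) by mouth on embryonic days 12, 13 and 14. Polyadenylated RNA was sequenced from the forebrain at embryonic day 15 (E15) and from the dentate gyrus at postnatal day 5 (P5) and at 12 weeks. A further group at 12 weeks was exposed to VPA before birth and given voluntary running. There was no running group without VPA, so an effect of running could be measured only in VPA mice. Each of the 7 groups had 3 libraries (n = 3), and values below are mean FPKM ± SD over the 3 libraries of a group.

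The deposited tables listed 1 value for each of 24322 gene symbols in all 21 libraries. Between 16116 and 16734 genes were above 0 in the E15 libraries and between 17251 and 17601 at P5, but only 12019 to 15210 at 12 weeks. Genes between 0 and 1 FPKM fell away most, from 3409 to 4565 per library at E15 to 517 to 1677 at 12 weeks. The median SD of a gene among replicates, in log2 units, was 0.113 in the E15 controls, 0.092 in the P5 controls and 0.335 in the 12-week controls. It reached 0.354 in the 12-week VPA group and 0.5 in the running group. Differences of the same size were therefore harder to detect at 12 weeks than at the younger ages.

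**Figure D1:**
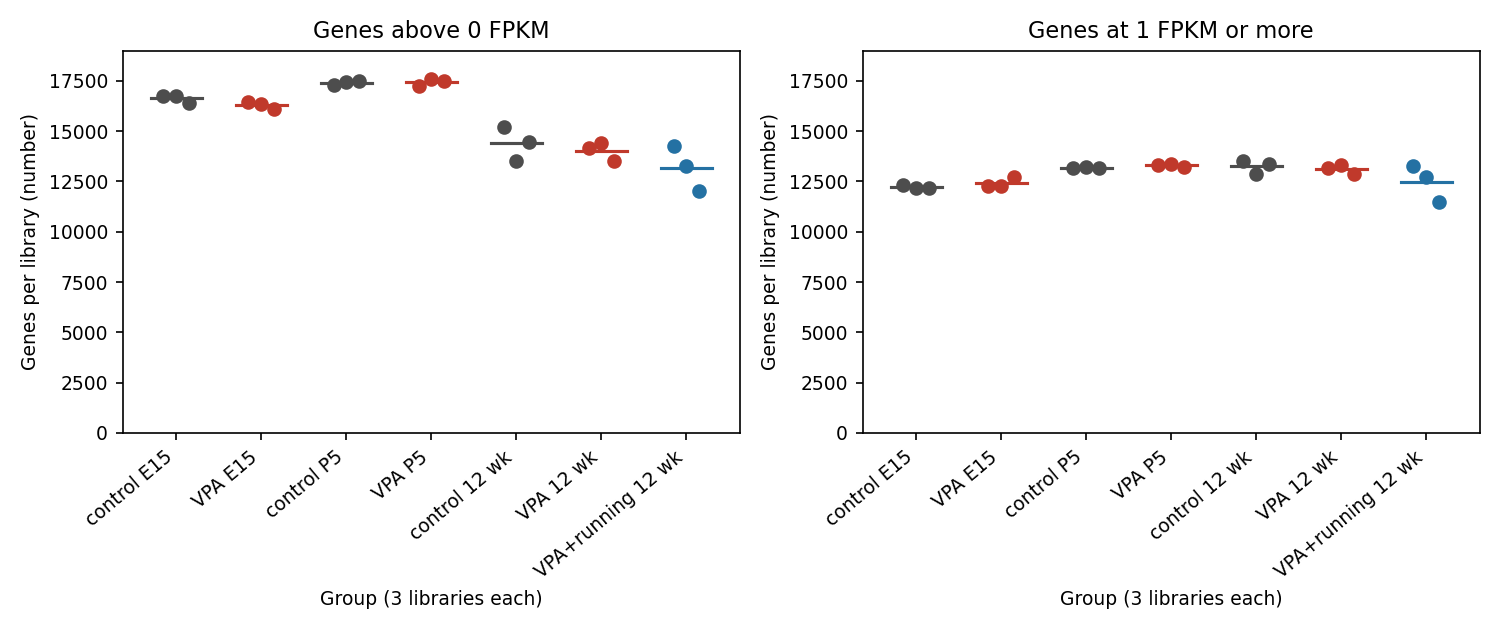
Genes above 0 FPKM (left) and genes at 1 FPKM or more (right) in each library. Points are libraries and lines are group means.

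The first comparison asked which transcripts differed in forebrain progenitors at E15, soon after the last dose. Genes of GABAergic neurons were higher in VPA libraries as a list, with all 12 tested members higher and a median log2 fold change of 0.69 (camera adjusted p = 3.87e-05; adjusted p = 0.808 with an estimated correlation). The vesicular GABA transporter gene Slc32a1 had 17.4 ± 1.57 in VPA and 10.2 ± 2.79 in control libraries (log2 fold change 0.74, adjusted p = 0.343). The interneuron peptide gene Sst had 79.6 ± 21.5 and 52.9 ± 6.29 (0.55, adjusted p = 0.44). The homeobox genes Dlx1 and Dlx5, which drive interneuron fate and were chosen after their values were seen, had 86.1 ± 14 against 50 ± 34.8 and 40.8 ± 2.21 against 22.04 ± 12.4. Control rep1 had 89.8 for Dlx1, as high as the VPA libraries at 85.2, 72.6 and 100.6, while the other controls had 34.8 and 25.3. Of the 12 GABAergic members, 1 passed when adjusted over the list alone and 0 passed over all genes.

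Immediate early genes were also higher as a list at E15, in 14 of 17 members with a median of 0.34 (camera adjusted p = 4.76e-05; adjusted p = 0.7 with an estimated correlation). Egr3, an activity-induced zinc finger factor, had 2.53 ± 0.212 in VPA and 0.826 ± 0.163 in control libraries (0.95, adjusted p = 0.171). Srf, the serum response factor that switches on many of these genes, had 31.7 ± 3.56 and 19.2 ± 1.02 (0.69, adjusted p = 0.171). Junb, an AP-1 subunit, had 7.18 ± 0.556 and 3.79 ± 0.712 (0.78, adjusted p = 0.291). Imprinted genes were higher in 13 of 15 members, with a median of 0.26 (camera adjusted p = 0.00165; adjusted p = 0.7 with an estimated correlation). Peg10 had 8.37 ± 0.981 and 4.02 ± 1.84 (0.96) and Peg3 had 21.1 ± 0.977 and 13.8 ± 2.83 (0.60). Adjusted over the list alone, 5 immediate early genes and 2 imprinted genes passed, against 0 of either over all genes.

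Hedgehog pathway genes were higher in 6 of 9 members at E15 (median 0.25, camera adjusted p = 0.0219) and Notch pathway genes in 11 of 14 (median 0.17, camera adjusted p = 0.0446). Both had adjusted p = 0.955 with an estimated correlation. The Hedgehog target genes Gli1 and Ptch1 had 1.73 ± 0.0575 against 0.979 ± 0.203 and 6.0 ± 0.382 against 3.79 ± 1.05. The Notch ligand gene Dll1 had 33.8 ± 9.31 and 19.7 ± 3.69 (0.73, adjusted p = 0.372), and Lfng, which modifies Notch receptors, had 6.11 ± 1.48 and 4.06 ± 0.837. GABA and glutamate receptor genes were higher in 14 of 20 members (median 0.15, camera adjusted p = 0.0393; adjusted p = 0.955 with an estimated correlation). Grik3, a kainate receptor subunit, had 30.2 ± 2.5 and 18.8 ± 1.98 (0.66, adjusted p = 0.195), whereas the GABA-A subunit gene Gabra2 was lower, at 11.1 ± 3.74 and 20.5 ± 1.25 (-0.87).

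Newborn neuron genes were lower in VPA libraries at E15 in 17 of 20 members, with a median of -0.07 (camera adjusted p = 0.033; adjusted p = 0.808 with an estimated correlation). Sox11, a factor of immature neurons, had 166 ± 1.06 in VPA and 225 ± 6 in control libraries (-0.44, adjusted p = 0.171). The adhesion gene Ncam1 had 63.6 ± 2.07 and 79.0 ± 4.71 (-0.31, adjusted p = 0.343). Ribosomal protein genes were lower in 69 of 76 members, with a median of -0.13 (camera adjusted p = 8.11e-05; adjusted p = 0.955 with an estimated correlation). Among single genes with the smallest p, the protocadherin gene Pcdh10 had 20.1 ± 0.194 and 13.8 ± 0.737 (0.52). The potassium channel subunit gene Kcng1 had 15.3 ± 0.677 and 9.6 ± 0.855 (0.62), and the zinc exporter gene Slc30a1 had 6.59 ± 1.06 and 3.07 ± 0.161 (0.89), each with adjusted p = 0.171. Genes of histone deacetylases, which VPA inhibits, had a median of -0.05 over 13 members (camera adjusted p = 0.281).

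Only 5 of 12345 genes passed the limma threshold at E15, and all 5 were small RNA genes that fell and were listed at 0 in the 3 VPA libraries. Mir7078 (ENSMUSG00000098483.1, chromosome 8, 117459265 to 117459328) had 207.3, 325.1 and 367.9 in the controls (adjusted p = 2.0e-05). Snord65 had 167.1, 393.2 and 118.7 (adjusted p = 0.00115) and Mir3057 had 27.4, 21.5 and 38.9 (adjusted p = 0.000364). Snord57 had 441.7, 86.6 and 235.2 (adjusted p = 0.00538) and Scarna6 had 6.01, 6.73 and 3.05 (adjusted p = 0.041). Their host transcripts and mature forms were not measured apart, because polyadenylated RNA was sequenced. These calls therefore do not show that the small RNAs themselves fell. Values of 0 in every VPA library also have no spread, which lowers the SE. No protein-coding gene passed, although 1301 genes had an unadjusted p < 0.05 where 617 would be expected by chance. The VPA and control values did not overlap in 17.5% of genes, against a chance share of 10%. The stem cell marker Nes had 17.4 ± 2.39 and 16.2 ± 1.86 (0.09, adjusted p = 0.788). The chemokine receptor gene Cxcr4 had 21 ± 8.41 and 23.5 ± 2.1 (-0.23, adjusted p = 0.778), and without VPA rep3 its log2 fold change turned to 0.11.

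The 5 small RNA genes were above 0 in the 3 control libraries alone, so without any of these they missed the filter and were not tested. Among the genes still tested, 0 passed without control rep2 or control rep3, and 7 rose without control rep1. Without VPA rep1 11 genes passed, all of them falls. VPA rep3 also held choroid plexus transcripts, chosen after their values were seen: Ttr was 9662 there and 8.75 to 131.4 in the other E15 libraries, and Enpp2 was 1296 there and at most 20.9 elsewhere. The same library had 214.9 for Apoe, where the other E15 libraries had 12.1 to 15.7.

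**Figure D2:**
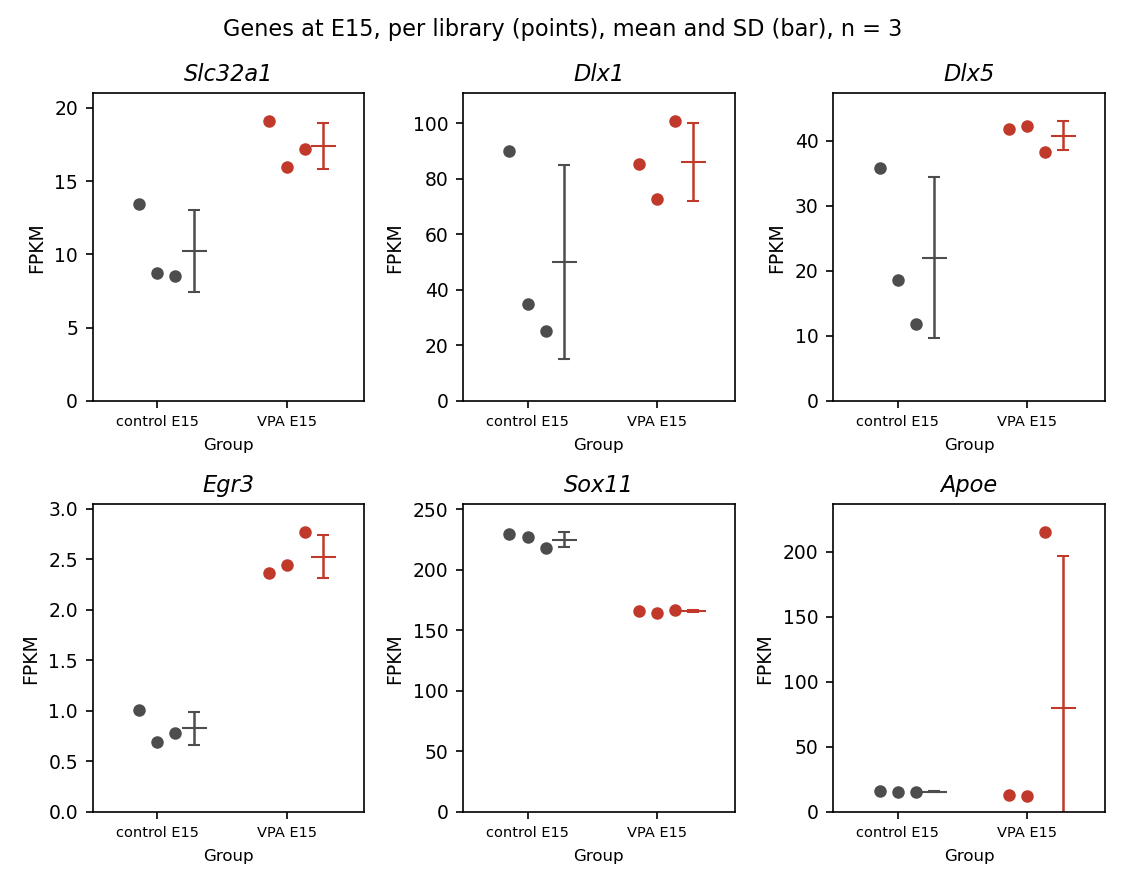
FPKM of 6 genes in control and VPA libraries at E15. Points are libraries and bars are mean ± SD (n = 3).

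At P5 the question was whether the exposure had left a difference in dentate gyrus progenitors after birth. Immediate early genes had more members past the threshold than any other list: 17 of 21 fell in VPA libraries, with a median log2 fold change of -1.18 (camera adjusted p = 1.02e-19; adjusted p = 0.424 with an estimated correlation). Fos (ENSMUSG00000021250.13, chromosome 12, 85473890 to 85477273) fell from 676 ± 53.3 to 186 ± 37.6 (-1.87, adjusted p = 0.00464). Its partner gene Fosb fell from 35.9 ± 4.64 to 11.4 ± 2.52 (-1.59, adjusted p = 0.01). The zinc finger factor gene Egr2 fell from 19.4 ± 4.05 to 5.63 ± 0.592 (-1.61, adjusted p = 0.0083) and the orphan nuclear receptor gene Nr4a1 from 133 ± 10.4 to 44.8 ± 13.5 (-1.59, adjusted p = 0.0195). Btg2 (ENSMUSG00000020423.6, chromosome 1, 134075170 to 134079120), an antiproliferative gene from the intermediate progenitor list, fell from 92.0 ± 4.26 to 42.9 ± 3.14 (-1.08, adjusted p = 0.00152). Egr1, Junb, Klf6, Jun and Ier2, chosen after their values were seen, fell by 1.47, 1.47, 1.27, 1.18 and 1.16. Adjusted over the immediate early list alone, 19 members fell and 1 rose.

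Stem cell and dividing cell genes were lower in the same libraries. All 16 neural stem cell genes were lower, with a median of -0.27 (camera adjusted p = 5.06e-06; adjusted p = 0.424 with an estimated correlation). The stem cell factor gene Sox2 fell from 96.3 ± 3.66 to 74.9 ± 5.77 (-0.36, adjusted p = 0.0462). The gliogenic factor gene Sox9, of the astrocyte list, fell from 41.0 ± 3.35 to 25.1 ± 0.695 (-0.69, adjusted p = 0.01), while Gjb6 of that list rose (0.66, adjusted p = 0.0468). The Notch effector gene Hes1 fell from 17.1 ± 1.84 to 11 ± 1.13 (-0.59, adjusted p = 0.0394). All 23 S phase genes (median -0.27, camera adjusted p = 6.83e-09; adjusted p = 0.424 with an estimated correlation) and all 22 G2/M genes (median -0.26, camera adjusted p = 5.06e-06; adjusted p = 0.49 with an estimated correlation) were lower. The replication licensing gene Cdt1 fell from 15 ± 0.692 to 11.4 ± 0.627 (-0.37, adjusted p = 0.0441), and Top2a, a topoisomerase of dividing cells, from 29.9 ± 2.67 to 19.4 ± 2.56 (-0.60, adjusted p = 0.0415). Over all genes 2 stem cell, 1 S phase and 1 G2/M member fell, against 9, 15 and 5 adjusted over the list alone. Intermediate progenitor genes were lower in 10 of 13 members (median -0.19, camera adjusted p = 0.0092; adjusted p = 0.443 with an estimated correlation).

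Hedgehog pathway genes were lower at P5 in all 9 members, with a median of -0.32 (camera adjusted p = 0.000341; adjusted p = 0.424 with an estimated correlation). Gli1 had 5.11 ± 0.525 in VPA and 8.05 ± 0.985 in control libraries (-0.57, adjusted p = 0.0501), and Ptch1 had 14.8 ± 1.48 and 20.8 ± 2.67 (-0.46, adjusted p = 0.0743). Chromatin regulator genes were lower in 25 of 27 members, with a median of -0.13 (camera adjusted p = 2.92e-05; adjusted p = 0.424 with an estimated correlation). The remodeller gene Chd7 fell from 33.3 ± 2.56 to 25.8 ± 0.822 (-0.35, adjusted p = 0.0474) and the histone demethylase gene Kdm6b from 51.0 ± 0.819 to 42.8 ± 1.07 (-0.25, adjusted p = 0.0423). In the list of heat shock and unfolded protein response genes, the 5 that fell were the endoplasmic reticulum genes Calr, Hsp90b1, Hspa5, Ddit3 and Xbp1 (list median -0.30, camera adjusted p = 0.000189; adjusted p = 0.424 with an estimated correlation). The chaperone gene Hspa5 fell from 155 ± 3.79 to 108 ± 8.98 (-0.52, adjusted p = 0.0218). Of 18 cholesterol genes 17 were lower (median -0.18, camera adjusted p = 6.16e-05; adjusted p = 0.49 with an estimated correlation), and Insig1 and Idi1 were among those that fell. The sterol sensor gene Insig1 fell from 65.0 ± 5.9 to 42.5 ± 1.77 (-0.60, adjusted p = 0.0195).

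Genes of vessel walls and connective tissue moved the other way. All 11 pericyte genes were higher in VPA libraries, with a median of 0.86 (camera adjusted p = 2.08e-06; adjusted p = 0.44 with an estimated correlation). Vtn (ENSMUSG00000017344.4, chromosome 11, 78499091 to 78502324), a matrix protein of pericytes, rose from 19.3 ± 2.38 to 50.3 ± 9.37 (1.33, adjusted p = 0.0145). The pericyte receptor gene Pdgfrb rose from 8.77 ± 0.306 to 18.9 ± 4.85 (1.0, adjusted p = 0.0381). Fibroblast genes were higher in 8 of 9 members (median 0.65, camera adjusted p = 2.63e-05; adjusted p = 0.424 with an estimated correlation), and Igf2, Col1a2, Foxc1 and Col3a1 rose. The growth factor gene Igf2 (ENSMUSG00000048583.16, chromosome 7, 142650766 to 142666816) rose from 11.7 ± 0.752 to 27.3 ± 5.25 (1.14, adjusted p = 0.0145), and the collagen gene Col3a1 from 2.06 ± 0.546 to 4.94 ± 1.08 (0.96, adjusted p = 0.0452). All 5 endothelial genes were higher (median 0.63, camera adjusted p = 0.00056; adjusted p = 0.424 with an estimated correlation). Their tight junction gene Cldn5 had 5.46 ± 1.03 and 2.21 ± 1.14 (1.06, adjusted p = 0.071).

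Genes of microglia and of red cells moved apart at P5. Microglial genes were higher in 11 of 12 members (median 0.57, camera adjusted p = 0.000189; adjusted p = 0.424 with an estimated correlation), and the lysosomal gene Laptm5 rose from 2.13 ± 0.392 to 4.17 ± 0.642 (0.72, adjusted p = 0.0472). The platelet chemokine gene Pf4 rose from 3.29 ± 0.376 to 8.86 ± 2.48 (1.17, adjusted p = 0.0341). All 6 erythroid genes were lower (median -1.99, camera adjusted p = 4.84e-05; adjusted p = 0.424 with an estimated correlation). The haemoglobin gene Hba-a1 fell from 497 ± 97 to 132 ± 52.6 (-1.98, adjusted p = 0.0354) and the haem synthesis gene Alas2 from 3.33 ± 0.695 to 0.792 ± 0.503 (-1.30, adjusted p = 0.0438). Markers of cells other than neural progenitors therefore moved with the treatment groups, in opposite directions for vessel walls and red cells.

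Other genes also changed at P5. The secreted Wnt antagonist gene Notum rose from 2.51 ± 0.311 to 7.36 ± 1.21 (1.25, adjusted p = 0.0127) and Dkk3, a secreted Dickkopf protein, from 31.8 ± 2.15 to 40.7 ± 1.73 (0.35, adjusted p = 0.0448). The Wnt list as a whole had a median of -0.11 over 22 members (camera adjusted p = 0.601). Rgs4, a brake on G protein signalling, rose from 9.12 ± 1.38 to 22.1 ± 3.91 (1.19, adjusted p = 0.0195), Sod3 from 2.79 ± 0.616 to 7.93 ± 2.3 (1.22, adjusted p = 0.0412) and Mcam from 7.77 ± 0.119 to 17.5 ± 4.76 (1.05, adjusted p = 0.0366). Sod3 codes for an extracellular superoxide dismutase and Mcam for an adhesion molecule of vessels. The gap junction gene Gjb6 rose from 0.421 ± 0.0812 to 1.25 ± 0.199 (0.66, adjusted p = 0.0468). Adamts1, a secreted metalloprotease gene, fell from 20.4 ± 1.76 to 6.62 ± 1.25 (-1.5, adjusted p = 0.00467).

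Mature neuron genes were higher as a list at P5 in 12 of 15 members, with a median of 0.24 (camera adjusted p = 0.00461; adjusted p = 0.49 with an estimated correlation). The neuronal enolase gene Eno2 had 14.1 ± 1.21 in VPA and 10.02 ± 1.28 in control libraries (0.45, adjusted p = 0.0672), and the kinase gene Camk2b had 120.4 ± 15.7 and 87.6 ± 7.82 (0.45, adjusted p = 0.0751). Ion channel genes were higher in 20 of 25 members (median 0.15, camera adjusted p = 0.00547) and receptor genes for GABA and glutamate in 17 of 22 (median 0.15, camera adjusted p = 0.0387), with adjusted p = 0.565 and adjusted p = 0.578 with an estimated correlation. The potassium channel gene Kcna1 had 6.53 ± 1.27 and 4.0 ± 0.18 (0.58). The AMPA receptor gene Gria1 had 51.4 ± 8.27 and 37.7 ± 3.27 (0.43). Oligodendrocyte precursor genes were higher in 7 of 11 members (median 0.11, camera adjusted p = 0.0355; adjusted p = 0.565 with an estimated correlation). Among them Sox10 had 40.4 ± 2.68 and 31.2 ± 3.79 (0.36, adjusted p = 0.0811) and Cspg4 had 15.9 ± 2.85 and 10.8 ± 1.75 (0.51, adjusted p = 0.108). Neither Nes, at 10.4 ± 0.621 and 12.7 ± 1.06 (-0.27, adjusted p = 0.114), nor Cxcr4, at 62.7 ± 3.78 and 58.2 ± 7.92 (0.11, adjusted p = 0.522), passed.

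Of 13328 genes at P5, 120 rose and 178 fell, 41 of them by more than 2-fold. The excess of falls was not kept in every alternative, with 607 rises and 606 falls under array quality weights, 380 and 369 without small RNA genes and 273 and 270 without VPA rep1. Only 1 of the 39 named genes past the threshold was tested and kept its call in every alternative. All 298 had VPA and control values that did not overlap, which a call from 3 libraries per group nearly requires. Among all genes 29.4% did not overlap, against a chance share of 10%. Small RNA genes made up 7 of the 298. Mir7006 was listed at 0 in the controls and had 523, 58.0 and 133.4 in VPA libraries (adjusted p = 0.0083). Mir3060, with 96.8, 86.0 and 56.6 in the controls, and Mir6976, with 185.6, 495.1 and 244.4, were listed at 0 in all VPA libraries. Mir6976 lies within the Srf gene on the same strand, so its values may stem from that transcript. The limits given for small RNA genes at E15 hold here too.

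The sexes of the P5 pups were mixed unequally between the groups. The Y-linked gene Ddx3y had 0, 0.0129 and 22.02 in the controls and 20.3, 19.1 and 20.8 in VPA libraries, and the X inactivation transcript Xist had 316.9, 308.5 and 2.65 against 1.93, 20.01 and 0.149. With a covariate for libraries without Y-linked transcripts, 10 genes passed and 1 of the 21 immediate early genes fell, while the median of that list was -1.21. The count of 298 became 23 without control rep1, 18 without control rep2, 500 without control rep3, 543 without VPA rep1, 32 without VPA rep2 and 107 without VPA rep3. The 17 immediate early genes that fell became 8 without control rep1, 6 without control rep2 and 7 without VPA rep2.

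**Figure D3:**
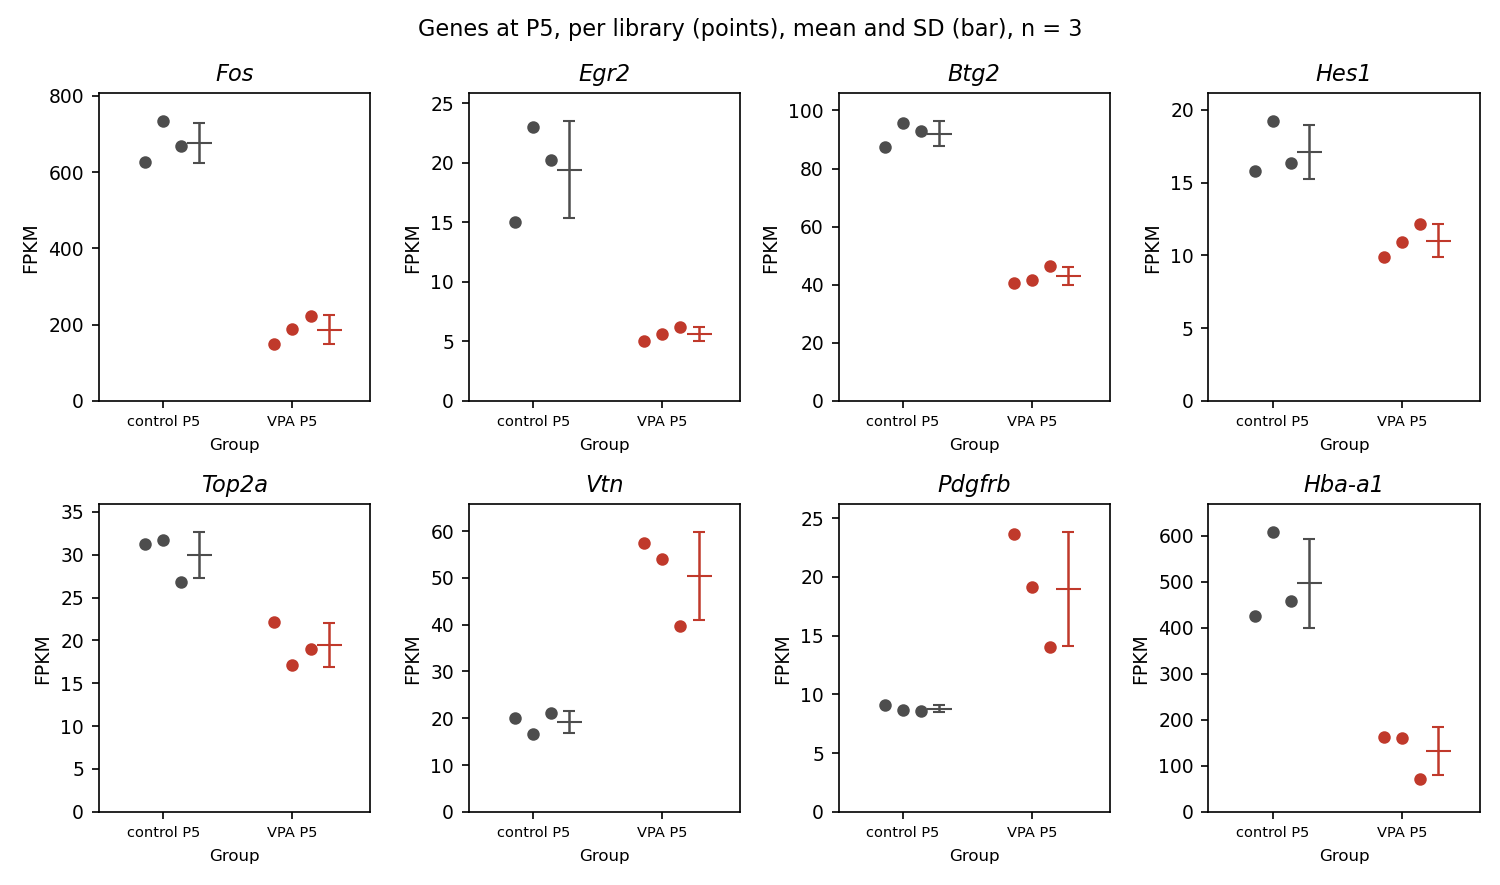
FPKM of 8 genes in control and VPA libraries at P5. Points are libraries and bars are mean ± SD (n = 3).

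At 12 weeks the comparison asked whether the adult dentate gyrus cells of exposed mice still differed. All 11 oligodendrocyte precursor genes were higher in VPA libraries, with a median of 0.96 (camera adjusted p = 2.81e-15; adjusted p = 0.283 with an estimated correlation). Gjc3 (ENSMUSG00000056966.7, chromosome 5, 137953461 to 137963098), a glial connexin gene, had 142 ± 8.55 in VPA and 61.2 ± 6.49 in control libraries (1.2, adjusted p = 0.162), the smallest adjusted p of the comparison. Neu4 (ENSMUSG00000034000.15, chromosome 1, 94020451 to 94028334), a sialidase gene, had 111 ± 9.47 and 52.5 ± 10.1 (1.09, adjusted p = 0.415). Lhfpl3 had 256 ± 46.3 and 114 ± 39.5 (1.19, adjusted p = 0.415). Pdgfra, the growth factor receptor gene of these cells, chosen after its values were seen, had 330.8 ± 87.1 and 154 ± 32.5. Adjusted over the list alone 8 members passed, against 0 over all genes.

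Astrocyte genes were lower in VPA libraries at 12 weeks in 16 of 17 members, with a median of -0.58 (camera adjusted p = 3.4e-07; adjusted p = 0.283 with an estimated correlation). The glutamate transporter genes Slc1a3, of the neural stem cell list, and Slc1a2 had 209 ± 28.8 against 367 ± 122 (-0.76, adjusted p = 0.609) and 99.03 ± 11.1 against 147 ± 14.4 (-0.56, adjusted p = 0.557). The glutamine synthetase gene Glul had 126 ± 17.8 and 219 ± 54.3 (-0.77, adjusted p = 0.557). Neural stem cell genes were lower in 11 of 16 members (median -0.49, camera adjusted p = 0.00701; adjusted p = 0.373 with an estimated correlation). Their member Ptprz1, a phosphatase gene, was higher, with 274 ± 18.7 in VPA and 185.5 ± 35.6 in control libraries (0.57, adjusted p = 0.619). Newborn neuron genes were lower in 18 of 19 (median -0.28, camera adjusted p = 1.01e-05; adjusted p = 0.283 with an estimated correlation). The neuronal tubulin gene Tubb3 had 292 ± 24.8 and 439.9 ± 59.8 (-0.58, adjusted p = 0.557) and Sox4, a factor of new neurons, had 161 ± 35.4 and 238 ± 6.07 (-0.58).

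Dividing cell genes were lower as well at 12 weeks. S phase genes were lower in 18 of 23 members (median -0.34, camera adjusted p = 0.00463) and G2/M genes in 19 of 22 (median -0.62, camera adjusted p = 0.000557), both with adjusted p = 0.283 with an estimated correlation. The replicative helicase gene Mcm6 had 34.0 ± 6.67 and 50.1 ± 0.648 (-0.57), and the mitotic cyclin gene Ccnb1 had 1.04 ± 0.381 and 5.39 ± 2.24 (-1.61). Vessel genes were lower too, the opposite of P5. Endothelial genes were lower in 12 of 13 members (median -1.08, camera adjusted p = 5.78e-06), pericyte genes in 12 of 12 (median -0.80, camera adjusted p = 5.88e-06) and fibroblast genes in 10 of 10 (median -0.76, camera adjusted p = 0.000201), each with adjusted p = 0.283 with an estimated correlation. Cldn5 had 50.2 ± 17.9 and 123 ± 71.9 (-1.2), and the contractile gene Myl9 had 70.8 ± 25.1 and 159.9 ± 64.9 (-1.14). Microglial genes were lower in 12 of 15 members (median -0.43, camera adjusted p = 0.0483; adjusted p = 0.567 with an estimated correlation). Single control libraries stood apart for these cells, with Csf1r at 42.6 in control rep1 against 3.72 and 6.19, and Cldn5 at 204.6 in control rep2 against 68.1 and 97.3.

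Immediate early genes were higher in VPA libraries at 12 weeks, in 19 of 21 members with a median of 0.49 (camera adjusted p = 5.01e-05; adjusted p = 0.283 with an estimated correlation). Fosb had 168 ± 44.1 and 72.2 ± 7.35 (1.18, adjusted p = 0.51) and Jun had 434 ± 27.2 and 267 ± 31.6 (0.70, adjusted p = 0.51). GABAergic genes were higher in 8 of 9 members (median 1.01, camera adjusted p = 0.00382) and ribosomal protein genes were lower in 74 of 76 (median -0.36, camera adjusted p = 6.09e-18), both with adjusted p = 0.283 with an estimated correlation. The GABA synthesis gene Gad1 had 23.2 ± 12.6 and 9.89 ± 1.54 (1.04), and the ribosomal gene Rps10 had 119 ± 17.9 and 236 ± 53.5 (-0.97). Cholesterol genes were lower in 16 of 18 members (median -0.21, camera adjusted p = 0.0076; adjusted p = 0.283 with an estimated correlation), and the squalene synthase gene Fdft1 had 14.9 ± 2.22 and 26.8 ± 6.95 (-0.78). Among genes with the smallest p, the adaptor gene Shc4 had 36.2 ± 7.29 and 8.32 ± 3.83 (2.07). Cntnap2, a neurexin relative in which mutations are linked to autism, had 8.68 ± 0.855 and 24.8 ± 4.22 (-1.40). Rnd2, a gene of migrating neurons, had 144 ± 11.4 and 286 ± 28.6 (-0.98), and the chromatin factor gene Prdm8 had 33.2 ± 0.203 and 60.3 ± 3.83 (-0.84), all with adjusted p = 0.415.

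None of 13847 genes passed the limma threshold at 12 weeks, and 885 had an unadjusted p < 0.05 where 692 would be expected. Group values did not overlap in 15.5% of genes, against a chance share of 10%. Sap25 was listed at 0 in all controls and had 12.6, 11.7 and 5.35 in VPA libraries. Cxcr4 (ENSMUSG00000045382.6, chromosome 1, 128588199 to 128592293) had 24.2 ± 8.2 in VPA and 46.9 ± 10.7 in control libraries (-0.96, adjusted p = 0.618). Nes had 10.1 ± 2.26 and 14.9 ± 4.09 (-0.50, adjusted p = 0.846). In a fit of all 21 libraries 533 of 14662 genes passed. That fit tested a different set of genes and pooled the variance with the E15 and P5 libraries, whose smaller spread understates that at 12 weeks. The count was 1 without control rep1, VPA rep1 or running rep3. The larger spread among these libraries left small power, since 44% of genes with a simulated log2 change of 2 were recovered here and 97% at P5.

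The comparison of VPA with running and VPA alone at 12 weeks asked what running changed in exposed mice. Oligodendrocyte precursor genes were lower with running in 11 of 11 members, with a median of -1.22 (camera adjusted p = 3.0e-14; adjusted p = 0.205 with an estimated correlation). Gjc3 had 54.4 ± 0.814 with running and 142 ± 8.55 without (-1.36, adjusted p = 0.0516). The complement-related synaptic ligand gene C1ql1 had 97.0 ± 12.9 and 245 ± 49.5 (-1.32, adjusted p = 0.0953), and Neu4 had 50.8 ± 3.17 and 111 ± 9.47 (-1.12, adjusted p = 0.0953). All 11 members passed when adjusted over the list alone, against 0 over all genes. The matrix gene Tnr had 30.8 ± 2.35 and 84.9 ± 3.42 (-1.43, adjusted p = 0.0527).

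Astrocyte genes were higher with running in 14 of 17 members, with a median of 0.69 (camera adjusted p = 9.33e-07; adjusted p = 0.237 with an estimated correlation). Slc1a2 had 201 ± 24.2 and 99.03 ± 11.1 (1.01, adjusted p = 0.0953) and the lipid enzyme gene Acsbg1 had 45.8 ± 9.36 and 16.4 ± 1.44 (1.41, adjusted p = 0.136). Slc1a3, of the neural stem cell list, had 578 ± 65.9 and 209 ± 28.8 (1.46, adjusted p = 0.0981). Neural stem cell genes were higher in 12 of 16 members (median 0.47, camera adjusted p = 0.000217; adjusted p = 0.27 with an estimated correlation). Hopx, a marker of quiescent stem cells, had 235 ± 67.3 and 66.7 ± 26.5 (1.83, adjusted p = 0.152). Intermediate progenitor genes were higher in 11 of 13 members (median 0.45, camera adjusted p = 0.00174; adjusted p = 0.205 with an estimated correlation). Eomes, a factor of these progenitors, had 142 ± 13.5 and 84.0 ± 37.8 (0.84), and Insm1, which drives their formation, had 56.6 ± 10.1 and 32.0 ± 6.04 (0.81). Adjusted over the list alone, 10 astrocyte genes, 4 stem cell genes and 1 intermediate progenitor gene were higher, against 0 over all genes.

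Cycle genes were higher with running, G2/M genes in 19 of 22 members (median 0.79, camera adjusted p = 1.06e-06; adjusted p = 0.227 with an estimated correlation) and S phase genes in 17 of 23 (median 0.29, camera adjusted p = 0.000325; adjusted p = 0.237 with an estimated correlation). Ccnb1 had 6.4 ± 1.53 and 1.04 ± 0.381 (1.85), Ccnb2 had 19.04 ± 8.74 and 4.71 ± 2.4 (1.80), and Mcm6 had 64.0 ± 13.3 and 34.0 ± 6.67 (0.89). Cholesterol genes were higher in 16 of 18 members (median 0.34, camera adjusted p = 7.23e-05; adjusted p = 0.205 with an estimated correlation), among them the sterol demethylase gene Cyp51 with 33.8 ± 5.33 and 18.8 ± 5.5 (0.84). Immediate early genes were lower in 20 of 21 members (median -0.70, camera adjusted p = 1.55e-09; adjusted p = 0.227 with an estimated correlation), and 13 of them passed over the list alone, against 0 over all genes. Junb had 77.0 ± 20.8 and 143 ± 12.7 (-0.91, adjusted p = 0.165) and Jun had 274 ± 46.3 and 434 ± 27.2 (-0.67, adjusted p = 0.203). Receptor genes for GABA and glutamate were lower in 20 of 24 members (median -0.47, camera adjusted p = 0.0154; adjusted p = 0.237 with an estimated correlation), and Gabra3 had 3.93 ± 1.97 and 15.04 ± 2.94 (-1.76).

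Other genes with small p for running were Dtna, an adaptor of the dystrophin complex in astrocytes, with 60.9 ± 7.36 and 20.9 ± 3.17 (1.5, adjusted p = 0.0577) and Islr, a secreted mesenchymal protein, with 42.0 ± 14.7 and 6.04 ± 2.18 (2.61, adjusted p = 0.0577). Pon2 had 41.6 ± 3.82 and 10.5 ± 2.75 (1.92, adjusted p = 0.0953), Dkk3 had 52.8 ± 10.4 and 18.5 ± 4.1 (1.47, adjusted p = 0.0953) and the protease inhibitor gene Serpine2 had 175 ± 26.8 and 428 ± 90.7 (-1.28, adjusted p = 0.0953). AA465934 was listed at 0 in all running libraries and had 8.46, 45.2 and 26.9 in VPA libraries (adjusted p = 0.0527). Cxcr4 had 59.2 ± 16.3 and 24.2 ± 8.2 (1.27, adjusted p = 0.185), and Nes had 10.8 ± 2.09 and 10.1 ± 2.26 (0.09, adjusted p = 0.94). None of 13847 genes passed the limma threshold, and 1566 had an unadjusted p < 0.05 where 692 would be expected. Group values did not overlap in 15.5% of genes, against a chance share of 10%. In the fit of all 21 libraries, with its different genes and understated spread, 1698 genes passed, and Cxcr4 had adjusted p = 0.0099. The count was 37 without running rep1 and 2 without VPA rep1.

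The running libraries also stood apart from one another. The choroid plexus genes Ttr and Folr1, chosen after their values were seen, had 0.088, 315.7 and 558 and 0, 3.38 and 6.38 in running rep1, rep2 and rep3. In VPA libraries Ttr had 18.1, 87.4 and 22.6 and Folr1 was listed at 0. Running rep3 had the fewest genes above 0, at 12019, and small RNA genes held 27.7% of its column sum.

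**Figure D4:**
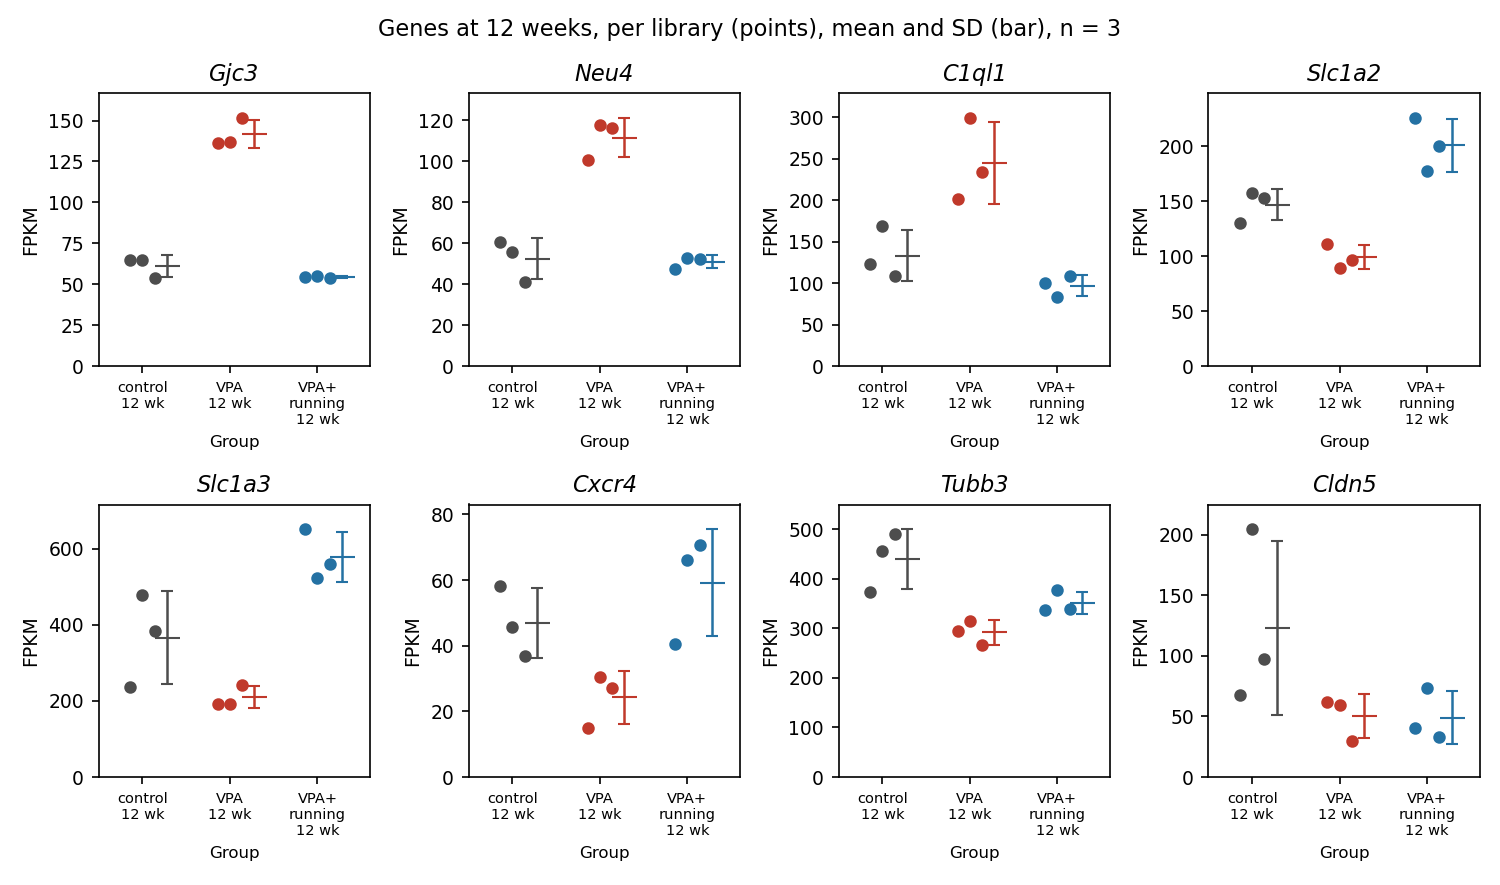
FPKM of 8 genes in control, VPA and VPA with running libraries at 12 weeks. Points are libraries and bars are mean ± SD (n = 3).

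Running VPA mice were also set against unexposed sedentary controls, which asked how far the running group lay from control. Exposure and running both differ between these groups, so no difference could be given to either alone. Genes of vessels and immune cells were lower. Microglial genes were lower in 15 of 15 members, with a median of -1.44 (camera adjusted p = 0.00173), although Csf1r in control rep1 stood apart as given above. Endothelial genes were lower in 12 of 13 members (median -0.80, camera adjusted p = 0.0177) and pericyte genes in 11 of 12 (median -0.58, camera adjusted p = 0.0102). These 3 lists had adjusted p = 0.609 with an estimated correlation. The microglial receptor gene Cx3cr1 had 2.35 ± 3.32 with running and 12.7 ± 13 in controls (-2.09), and Acta2, an actin of vessel walls, had 6.01 ± 4.89 and 22.5 ± 2.81 (-2.19). Immediate early genes were lower in 16 of 21 members (median -0.32, camera adjusted p = 0.00997) and glycolysis genes in 14 of 17 (median -0.29, camera adjusted p = 0.029), both with adjusted p = 0.609 with an estimated correlation.

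G2/M genes were higher than in controls in 16 of 22 members (median 0.28, camera adjusted p = 0.0409; adjusted p = 0.609 with an estimated correlation), and the spindle gene Tpx2 had 24.7 ± 9.8 and 10.5 ± 3.34 (1.14). Ribosomal protein genes were lower in 63 of 76 (median -0.22, camera adjusted p = 0.000178; adjusted p = 0.609 with an estimated correlation). Dtna had 60.9 ± 7.36 and 24.4 ± 2.37 (1.28, adjusted p = 0.351), Sat2 had 22.9 ± 3.24 and 4.13 ± 2.34 (2.31, adjusted p = 0.443) and the respiratory chain gene Cox8a had 96.9 ± 17.8 and 266 ± 67.3 (-1.44). Fv1 was listed at 0 in all running libraries and had 6.42, 7.79 and 13.9 in controls (adjusted p = 0.351). Cxcr4 had 59.2 ± 16.3 and 46.9 ± 10.7 (0.31, adjusted p = 0.794), and the log2 fold change of Nes was -0.41 (adjusted p = 0.744). None of 13847 genes passed the limma threshold, 1074 had an unadjusted p < 0.05 where 692 would be expected, and values did not overlap in 13.1% against a chance share of 10%. The count was 886 in the fit of all 21 libraries, with its different genes and understated spread. It was 12 without running rep1 and 1 without control rep3 or running rep3.

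Whether running moved genes back toward control values was asked by setting the effect of VPA against the effect of running in VPA mice, gene by gene. The correlation was -0.52 across genes, which are not independent replicates. Both effects share the same 3 VPA libraries, and data simulated with no effect gave a mean correlation of -0.498 over 20 runs, with a range of -0.525 to -0.473. Of 239 genes at an unadjusted p < 0.01, 95.4% moved in opposite directions, where the simulated data gave 89.6% with a range of 86.6% to 93.9%. The number of such genes was also above the simulated 117 to 174, and so was the size of the covariance, at -0.216 against -0.153 to -0.129. Of 100 regroupings of the libraries, 28 gave as high a share of opposite genes, 5 as many genes and 35 as low a covariance. Gjc3, Neu4, C1ql1, Slc1a2, Slc1a3 and Cxcr4 had running values on the control side of their VPA values, and so did the oligodendrocyte precursor and astrocyte lists. For each of these genes the running mean lay beyond the control mean. Neu4 had 50.8 with running, 52.5 in control and 111 in VPA libraries, and Slc1a3 had 578, 367 and 209. Apart from Cxcr4, these genes were named for small p in comparisons that share the VPA libraries. The measures that exceeded the simulations did not separate a return toward control from the shared libraries in the regroupings.

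Control libraries were next compared between ages to describe the cells. From E15 forebrain to P5 dentate gyrus, glial genes rose. Astrocyte genes rose in 16 of 17 members, with a median of 3.60 (camera adjusted p = 4.39e-21), and all 11 oligodendrocyte precursor genes rose, with a median of 4.59 (camera adjusted p = 7.24e-21). The filament gene Gfap rose from 0.377 ± 0.0649 to 97.1 ± 4.87 (6.16, adjusted p = 1.29e-12), the lipid carrier gene Apoe from 15.5 ± 0.207 to 846 ± 97.2 (5.68, adjusted p = 6.52e-06) and the glial fate factor gene Olig1 from 3.49 ± 1.07 to 205 ± 17.9 (5.55, adjusted p = 7.47e-12). Prox1, the factor of dentate granule cells, rose from 2.95 ± 0.419 to 144 ± 10.8 (5.21, adjusted p = 1.17e-11) and the calcium-binding gene Calb2 from 10.6 ± 0.621 to 404 ± 17 (5.13, adjusted p = 1.29e-12). Notch pathway genes rose in 12 of 17 members (median 1.29, camera adjusted p = 2.36e-07), with Hes5 going from 7.5 ± 0.617 to 89.0 ± 13.5 (3.40). These 3 lists kept adjusted p = 0.00919, adjusted p = 0.0114 and adjusted p = 0.0114 with an estimated correlation.

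Stem cell genes rose in 9 of 16 members (median 1.48, camera adjusted p = 1.15e-05; adjusted p = 0.134 with an estimated correlation), with Hopx going from 5.89 ± 0.589 to 128 ± 17.8 (4.23, adjusted p = 4.58e-08). Immediate early genes rose in 16 of 21 (median 2.5, camera adjusted p = 1.37e-11; adjusted p = 0.0576 with an estimated correlation), and Fos went from 10.1 ± 3.68 to 676 ± 53.3 (5.97, adjusted p = 8.24e-12). Newborn neuron genes fell in 15 of 20 members and rose in 2 (median -1.03, camera adjusted p = 7.86e-13; adjusted p = 0.0576 with an estimated correlation). The cortical factor gene Bcl11b fell from 38.4 ± 2.65 to 2.44 ± 0.681 (-3.53). GABAergic genes fell in 6 of 12 members, 9 when adjusted over the list alone (median -1.46, camera adjusted p = 1.43e-08; adjusted p = 0.0576 with an estimated correlation). The interneuron factor gene Lhx6 fell from 39.1 ± 0.931 to 0.624 ± 0.193 (-4.63, adjusted p = 8.69e-12). The guidance receptor gene Robo1 fell from 39.7 ± 0.367 to 5.18 ± 0.234 (-2.72), while Cxcr4 rose from 23.5 ± 2.1 to 58.2 ± 7.92 (1.27, adjusted p = 0.00353). The change in Nes was -0.33 (adjusted p = 0.3).

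Of 14662 genes, 2110 rose and 928 fell from E15 to P5, and the median of all genes was 0.14, small beside the list medians above. The counts were 1818 and 1311 after median-of-ratios scaling and 1392 and 1278 after quantile scaling. Region and age changed together, and so did dissection, so none of these differences could be given to age alone.

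From P5 to 12 weeks, vessel and myelin genes were higher in control libraries. These libraries had 17297 to 17503 genes above 0 at P5 and 13529 to 15210 at 12 weeks. Their median SD among replicates was 0.092 and 0.335. Age changed together with detection and spread, so the differences below could not be given to age alone. Endothelial genes rose in 12 of 13 members (median 3.80, camera adjusted p = 2.08e-18) and pericyte genes in 12 of 12 (median 2.73, camera adjusted p = 2.08e-18), both with adjusted p = 0.0243 with an estimated correlation. Vtn rose from 19.3 ± 2.38 to 1120 ± 434 (5.71, adjusted p = 3.74e-09), Cldn5 from 2.21 ± 1.14 to 123 ± 71.9 (5.18) and the endothelial surface gene Ly6c1 from 0.511 ± 0.532 to 132 ± 12.7 (6.51, adjusted p = 7.14e-08). Oligodendrocyte precursor genes rose in 9 of 11 members (median 1.65, camera adjusted p = 5.24e-14) and myelinating genes in 6 of 12 (median 1.86, camera adjusted p = 7.37e-10), both with adjusted p = 0.0243 with an estimated correlation. Neu4 rose from 2.61 ± 0.806 to 52.5 ± 10.1 (3.89, adjusted p = 6.0e-10). Heat shock and unfolded protein genes rose in 8 of 13 members (median 0.70, camera adjusted p = 9.39e-10; adjusted p = 0.0243 with an estimated correlation), and Hspb1 went from 0.351 ± 0.121 to 50.8 ± 5.6 (5.26). Interferon genes rose in 7 of 15 (median 1.60, camera adjusted p = 9.82e-07; adjusted p = 0.0308 with an estimated correlation), and Ifi27 went from 3.15 ± 0.474 to 87.0 ± 19.9 (4.39).

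Single genes of radial glia moved both ways by 12 weeks, and the list had a median of -0.03 (camera adjusted p = 0.239). The matrix gene Tnc fell from 106 ± 21.6 to 8.64 ± 4.87 (-3.56) and the fatty acid binding gene Fabp7 from 1826 ± 141 to 426 ± 188 (-2.18), while the factor gene Sox1 rose from 17.3 ± 0.88 to 28.8 ± 6.1 (0.69, adjusted p = 0.041). Astrocyte genes also moved both ways, with 6 rises and 3 falls among 17 (camera adjusted p = 0.219). The calcium-binding gene S100b rose from 9.34 ± 0.287 to 62.1 ± 15.9 (2.58) and Gjb6 from 0.421 ± 0.0812 to 15.1 ± 2.41 (3.50), and the water channel gene Aqp4 fell from 44.3 ± 2.59 to 7.63 ± 0.29 (-2.39). Cholesterol genes fell in 8 of 18 members and rose in 1 (median -0.60, camera adjusted p = 2.48e-06; adjusted p = 0.0243 with an estimated correlation), and Hmgcs1 fell from 147 ± 6.71 to 55.1 ± 1.71 (-1.40). All 22 G2/M genes were lower, 3 of them past the threshold and 6 over the list alone (median -0.93, camera adjusted p = 2.26e-05; adjusted p = 0.208 with an estimated correlation). The proliferation marker Mki67 fell from 21.1 ± 2.14 to 11.1 ± 1.41 (-0.88). Reln, the guidance glycoprotein of Cajal-Retzius cells, fell from 38.4 ± 13 to 2.41 ± 2.86 (-3.79) and the immature neuron gene Dcx from 156 ± 3.05 to 106 ± 11.1 (-0.55). Cxcr4 had a log2 fold change of -0.32 (adjusted p = 0.545) and Nes of 0.19 (adjusted p = 0.62).

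In all, 1064 genes rose and 784 fell from P5 to 12 weeks, and the 10 largest falls were small RNA genes listed at 0 at 12 weeks, such as Snord34 with 848, 205.6 and 608.9 at P5. The count of 1848 was 1144 without P5 control rep1, 1139 without P5 control rep2 and 1179 without P5 control rep3. The pooled variance of this fit understates the spread at 12 weeks, and 34 of the 96 named genes past the threshold were tested and kept their call in every alternative.

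Differences in the VPA effect between ages were tested directly. E15 cells came from the forebrain and later cells from the dentate gyrus, so differences from E15 could not be given to age alone. Interactions with P5 also carry its unequal sex mix, and the covariate for Y-linked transcripts was not run for the interactions. Between P5 and E15 the effect fell for Fos, Junb, Nr4a1, Klf6, Btg2 and Jun, by 2.62 (adjusted p = 0.0014), 2.25 (adjusted p = 0.000354), 2.18 (adjusted p = 0.0377), 1.66 (adjusted p = 0.00102), 1.53 (adjusted p = 0.00633) and 1.46 (adjusted p = 0.00928) log2 units. Fos had 17.6 ± 5.07 in VPA and 10.1 ± 3.68 in control libraries at E15, and Junb had 32.4 ± 5.41 and 91.0 ± 10.2 at P5. Immediate early genes were the only list kept with an estimated correlation, with a median of -1.46 over 21 members, of which 5 fell and 12 fell over the list alone (camera adjusted p = 7.89e-52; adjusted p = 0.000412 with an estimated correlation). Txnip, an inhibitor of thioredoxin, rose by 1.97 (adjusted p = 0.00431), from 8.63 ± 3.37 in VPA and 24.6 ± 1.28 in control libraries at E15 to 28.3 ± 5.25 and 19.5 ± 1.31 at P5. Pericyte genes had a higher effect at P5 in 12 of 12 members (median 1.15, camera adjusted p = 1.98e-14; adjusted p = 0.0537 with an estimated correlation). Nes (-0.36) and Cxcr4 (0.34) did not pass. Only 283 genes had an unadjusted p < 0.05 where 733 would be expected by chance. The pooled variance of this fit includes the larger spread at 12 weeks, so it overstates the spread at E15 and P5. In all 2 genes rose and 12 fell, and the count was 22 without E15 control rep1 and 8 without P5 control rep2. It changed far more with array quality weights and with only the groups compared in the fit, as given under the processing below.

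Between P5 and 12 weeks the effect rose for several immediate early genes. The P5 part of these differences rests on groups with an unequal sex mix. There the covariate for Y-linked transcripts left 1 of the 17 immediate early calls, and it was not run for this interaction. Fosb rose by 2.77 (adjusted p = 0.0105), Nr4a1 by 2.49 (adjusted p = 0.00907) and Fos by 2.45 (adjusted p = 0.00289). The effect on Btg2, of the intermediate progenitor list, rose by 1.12 (adjusted p = 0.0394). Btg2 itself had 106.3 ± 4.71 in VPA and 105.3 ± 24 in control libraries at 12 weeks. Fos had 799 ± 84.3 in VPA and 539 ± 101 in control libraries at 12 weeks. Immediate early genes had a median of 1.56, and 8 of 21 rose (camera adjusted p = 6.49e-21; adjusted p = 0.0329 with an estimated correlation). Pericyte genes had a median of -1.47 (camera adjusted p = 8.86e-12; adjusted p = 0.162 with an estimated correlation), and Vtn fell by 2.31 (adjusted p = 0.0305), with 543 ± 126 in VPA and 1120 ± 434 in control libraries at 12 weeks. The potassium channel regulator gene Abcc9 fell by 1.99, the proteoglycan gene Bgn by 2.0 and Cntnap2 by 1.73 (adjusted p = 0.00289). Oligodendrocyte precursor genes had a higher effect at 12 weeks in 10 of 11 members (median 0.78, camera adjusted p = 7.83e-07; adjusted p = 0.243 with an estimated correlation). Cxcr4 had -1.07 (adjusted p = 0.331) and Nes -0.24.

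In all 37 genes rose and 20 fell between P5 and 12 weeks. These calls rest on the fit of all 21 libraries, whose pooled variance understates the spread at 12 weeks: Cntnap2 had adjusted p = 0.415 within 12 weeks. Only 1 of the 21 named genes past the threshold was tested and kept its call in every alternative. The count of 57 was 18, 10 and 15 without P5 control rep1, rep2 and rep3, and 18, 16 and 23 without P5 VPA rep1, rep2 and rep3. It was 224 without 12-week control rep1, 25 without 12-week control rep3, 118 without 12-week VPA rep2 and 30 without 12-week VPA rep3.

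Between 12 weeks and E15, Cntnap2 fell by 1.83 (adjusted p = 0.00858), with 19.01 ± 0.931 in VPA and 13.9 ± 1.3 in control libraries at E15, and Rnd2 fell by 1.37 (adjusted p = 0.0368). The adhesion gene Opcml rose by 1.72 (adjusted p = 0.0193), the glutamate transporter gene Slc1a1 by 1.38 (adjusted p = 0.0209) and the transaminase gene Gpt2 by 1.08 (adjusted p = 0.0368). Oligodendrocyte precursor genes had a higher effect at 12 weeks in 11 of 11 members (median 0.85, camera adjusted p = 9.42e-10; adjusted p = 0.36 with an estimated correlation). At E15, however, Neu4 was listed at 0 in both groups, and Olig1 had 2.84 ± 0.66 in VPA and 3.49 ± 1.07 in control libraries. For such genes the interaction restates the difference at 12 weeks. Nes had -0.60 and Cxcr4 -0.73. In all 8 genes rose and 4 fell, with the same limit of the pooled variance. A replicate block and array quality weights each left 0 of these 12 calls, and 7 of 100 splits of the libraries gave as many genes. The count of 12 was 1 without E15 control rep2, E15 VPA rep2, 12-week control rep3 or 12-week VPA rep3, and 3 without E15 control rep3. It was 7 without E15 VPA rep1, 64 without 12-week control rep1, 21 without 12-week VPA rep1 and 42 without 12-week VPA rep2.

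No gene passed in the same direction at more than 1 age, but with 0 genes past the threshold at 12 weeks and 5 at E15 at most 0.0386 shared genes would be expected, so this count was not informative. The VPA effects of E15 and P5 had a correlation of -0.037 over 12054 genes, those of P5 and 12 weeks -0.014 over 12889 and those of E15 and 12 weeks 0.058 over 11948, with genes not independent replicates. At an unadjusted p < 0.01, 12 genes were higher at both P5 and 12 weeks, the oligodendrocyte genes Sox10, Sox8 and Pllp among them, where 5.67 would be expected (Fisher exact p = 0.0142). Another 3 were lower at both of these ages where 4.75 would be expected (Fisher exact p = 0.633), and 9 were higher and then lower where 4.36 would be expected (Fisher exact p = 0.0414). The reverse held for 9 where 6.19 would be expected (Fisher exact p = 0.216). Between E15 and 12 weeks 6 were lower at both ages, including Bgn, the collagen chaperone gene Serpinh1 and S100a10, where 1.06 would be expected (Fisher exact p = 0.000665), and 4 were higher where 1.29 would be expected (Fisher exact p = 0.0405). Between these ages 2 were higher and then lower where 1.08 would be expected (Fisher exact p = 0.295), and 4 lower and then higher where 1.27 would be expected (Fisher exact p = 0.038). Between E15 and P5 16 were higher at both ages where 5.82 would be expected (Fisher exact p = 0.000235), and 3 were lower at both where 7.43 would be expected (Fisher exact p = 0.125). The larger excess was of opposite changes, with 27 higher at E15 and lower at P5 where 7.53 would be expected (Fisher exact p = 5.93e-09). Another 7 were lower at E15 and higher at P5 where 5.75 would be expected (Fisher exact p = 0.52). Region also changed between E15 and the later ages. All these Fisher tests treat genes as independent. Genes that move together make their p values too small, so these do not measure spread between libraries.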

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

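None of the tests here was chosen only after seeing the result, and the genes named are those the interaction tests ranked first.

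The VPA effect differed between P5 and E15 for 14 genes. Mir7006 rose by 7.59 and Txnip by 1.97, while Mir6976 (-8.15), Mir3060 (-6.30), Fos (-2.62), Junb (-2.25) and Nr4a1 (-2.18) fell. Between 12 weeks and P5 it differed for 57 genes, with rises for Mir6976 (8.15), Mir3060 (6.30), Sap25 (3.60), Rep15 (3.14) and Fosb (2.77) and falls for Mir7006 (-7.33), Vtn (-2.31), Tmem204 (-2.24), Bgn (-2) and Abcc9 (-1.99). Between 12 weeks and E15 it differed for 12 genes, with rises for Mir568 (14.2), Mir7078 (8.19), Opcml (1.72), Slc1a1 (1.38) and Gpt2 (1.08) and falls for Cntnap2 (-1.83) and Rnd2 (-1.37). The small RNA genes among these had groups listed at 0 at 1 or more ages, so their sizes depend on the added 1 FPKM. Comparisons with E15 also change the region, and those with P5 carry its unequal sex mix. Groups of 3 libraries were too small to test for single extreme values.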

How the results depend on the processing

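Tests added only after the results were seen were the removal of small RNA genes, the covariate for Y-linked transcripts, the removal of each running library for VPA against control at 12 weeks, and the counts of list members. Of 194 alternatives to 13 results 115 left the result the same and 79 changed it; the cause was not tested. Counts of genes past the threshold changed by setting as follows. A pseudocount of 0.1 gave 3 instead of 0 for running against VPA. No filter gave 3 instead of 5 at E15, 36 instead of 298 at P5, 1 for running against VPA and 30 instead of 14 for P5 minus E15. A filter at 5 FPKM gave 6 for running against VPA and 7 instead of 12 for 12 weeks minus E15. Quantile scaling gave 9 for running against VPA. Array quality weights gave 347 at E15, 1213 at P5, 11 at 12 weeks, 4 for running against VPA, 10238 instead of 3038 for P5 against E15, and 2494, 19 and 0 for the interactions of 14, 57 and 12 genes. No trend gave 22 for 12 weeks minus E15. Without small RNA genes the counts were 0 at E15, 749 at P5 and 5 for running against VPA, and with the Y-linked covariate 10 at P5. All 21 libraries in the fit, which also changed the genes tested, gave 3 at E15, 15 at P5, 533 at 12 weeks, 1698 for running against VPA and 886 for running against control. Only the groups compared gave 8033 for P5 against E15 and 157 for P5 minus E15.

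Leaving out 1 library gave 0 to 11 at E15, 18 to 543 at P5, 0 to 1 at 12 weeks, 0 to 37 for running against VPA, 0 to 12 for running against control, 2271 to 2552 for P5 against E15 and 1139 to 2288 for 12 weeks against P5. The interactions ranged from 8 to 22 for P5 minus E15, 10 to 224 for 12 weeks minus P5 and 1 to 64 for 12 weeks minus E15. Camera called 140 lists, of which 12 were kept with an estimated correlation, while fry called 59. The correlation of VPA and running effects of -0.52 was -0.859 over genes with an unadjusted p under 0.01. These genes were selected by their VPA effect, which shares its VPA libraries with the running effect, so selection alone makes the correlation more negative. No simulated value was made for the selected genes. The overlap between ages of 0 genes was 44 at an unadjusted p under 0.01. Of the named genes past the threshold, 0 of 5 at E15, 1 of 39 at P5, 64 of 104 for P5 against E15, 34 of 96 for 12 weeks against P5, and 5 of 12, 1 of 21 and 0 of 9 for the interactions were tested and kept their call in every alternative; none reversed. The 17 immediate early genes that fell at P5 were 8 without a filter, 7 with all 21 libraries and 1 with the Y-linked covariate.

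A block for replicate number gave 70 at P5, 1230 for P5 against E15, 347 for 12 weeks against P5, and 9, 9 and 0 for the interactions. Residuals of libraries with the same number had correlations of 0.12, 0.086 and 0.22 at E15, where other pairings reached 0.038, but of 0.096, 0.039 and 0.0046 at P5 and of -0.082 to 0.017 at 12 weeks, so the numbers did not pair the libraries throughout.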

Other observations

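The list of ventral forebrain genes, the test of dilution at P5 and the tests of precursor share and vascular share at 12 weeks were chosen only after seeing the result, and the other tests were set before.

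Ventral forebrain genes were higher in VPA libraries at E15 in 13 of 13 members, with a median log2 fold change of 0.971 (quartiles 0.702 and 1.46), and 2 passed over the list alone. At P5 6 of 8 were lower (median -0.216, 0 past the threshold over the list alone), and at 12 weeks 7 of 8 were higher (median 0.873, 1 past it). Dorsal forebrain genes at P5 were lower in 6 of 8 (median -0.178, 4 past it). At 12 weeks dorsal forebrain genes were lower in VPA libraries in 8 of 8 members, with a median of -0.427 and 0 past the threshold over the list alone. With running they were higher than in VPA alone in 8 of 8, with a median of 0.63 and 4 past it, and higher than in control in 6 of 8, with 0 past it.

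For the lower immediate early genes at P5, the sex mix was tested by setting the VPA mean against the control library with Y-linked transcripts, which gave a median of -1.21 with quartiles of -1.48 and -0.75. Against the 2 other control libraries the median was -1.12, and the bound set beforehand against a sex effect was met, but 1 library gives no spread among such controls, so the bound was too weak and the question stays open. With the covariate the list median went from -1.18 to -1.21 and the median SE of members from 0.132 to 0.175, and 1 call was left. A stronger stress response to dissociation in the controls may add to it: heat shock genes of dissociation had a median of -0.182 and ranged from -0.332 to 0.388, which leaves it open. The share of vascular and fibroblast cells was not estimated. Dilution by them would not by itself raise the mature neuron and oligodendrocyte precursor lists, most members of which were higher at P5. It could lower stem cell genes by as much as they changed, -0.272 with quartiles of -0.407 and -0.187. A dilution of that size, acting on both lists alike, would not lower immediate early genes by -1.18. That both lists stem from the same cells was not tested, and the comparison was chosen after its values were seen.

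For the higher oligodendrocyte precursor genes at 12 weeks, a larger share of precursors among the sorted cells stays open. That 11 of 11 members were higher, with an interquartile range of 0.231, restates the pattern and does not test it. Fewer vascular cells in the VPA libraries would be likely to raise astrocyte genes as well, and their median was -0.58 with quartiles of -0.733 and -0.434. Loss of low transcripts in shallow libraries would be unlikely to raise members at 20 FPKM or more. All 11 members had such a mean, so their median of 0.956, with a range of 0.453 to 1.19, is that of the whole list.

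The ventral genes at E15 may reflect more ventral tissue in the VPA dissections. Dorsal genes should then be lower, and their median of -0.0527, with quartiles of -0.247 and 0.107, left this open. A direct effect on interneuron genes could give the same values.

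Splitting the libraries in other ways tested the counts. The 10 splits of 6 libraries were too few for a share under 0.05. At E15 the real count of 5 was met by 2 of 10 splits, with 5 as the highest other, and at P5 the real count of 298 by 1 of 10, with 6 as the highest other. At 12 weeks the real counts of 0 were met by all 10 of 10, with 4, 3 and 2 as the highest other for VPA, running against VPA and running against control. The ages gave 3038 and 1848, each met by 1 of 10, with 1 as the highest other. Among 100 splits the interaction of P5 minus E15, with 14, and that of 12 weeks minus P5, with 57, were each met by 1, with 6 and 20 as the highest other. The interaction of 12 weeks minus E15, with 12, was met by 7 of 100, with 16 as the highest other, so that count is in line with an arbitrary split.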
